A study of Homo sapiens with 12 samples.

How the data were processed

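Deposited gene tables of 12 libraries were analysed, made from polyadenylated RNA of IMR90 lung fibroblasts. Per the labels, cells were on plastic or a 2 kPa gel and received 100 or 250 nM doxorubicin for 24 h, followed by at least 8 days of culture. The titles give doses in nM and the treatment protocol gives the same numbers in µM, and the design names a hydrogel where the growth protocol names PDMS-coated plates. The wording of the titles is used here. Other stiffnesses, doses and untreated, proliferating or quiescent controls named in the protocols were not among the samples analysed.

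The submitters' processing notes name Trimmomatic, STAR, RSEM and DESeq2 1.36.0 and the genome build GRCh38. The versions of the other tools, the annotation release and the strand setting are not given in the sources used here. The names of the 250 nM files mention molecular identifiers, and whether reads were collapsed by them is not given. The expected count values were deposited as RSEM gene estimates, per the file headers, in fractional reads assigned to a gene. The TPM values were deposited beside them, scaled for transcript length and library total by RSEM before deposition, per the file headers. FPKM, gene length and effective length columns were also deposited and were not tested. The files held 61541 gene identifiers. Symbols came from the name table supplied with the data and from GENCODE 29, which also gave coordinates, biotypes and transcript sequences for GC content.

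Expected counts were rounded and analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the 4 groups, which left 12329, and libraries were scaled by TMM. A quasi-likelihood model with 1 mean per group and 8 residual degrees of freedom gave 6 comparisons, which were gel against plastic at each dose, their average over both doses, the difference between the doses, and 250 against 100 nM on each substrate. P-values were adjusted by the method of Benjamini and Hochberg within a comparison and called under 0.05. Gene values are CPM, counts scaled to the effective library size, with the SD of 3 libraries, and folds are fitted by edgeR. Principal components used log2 CPM with a prior count of 2.

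The comparisons, the main alternatives, 27 gene lists with 754 genes and the rule for naming genes were fixed before the data were examined. Named were 16 core genes in the gel comparisons, the 5 protein-coding genes with the largest rise and the 5 with the largest fall in a comparison of 2 groups (called, mean CPM of at least 5, groups not overlapping), and up to 4 called members of a list with mean CPM of at least 1. Some named genes were left out for length, as were genes at 0 in a group. The result of 1 core gene is not reported here. Lists were tested by camera in limma 3.58.1 with a preset correlation between genes of 0.01 and again with an estimated correlation, adjusted over the 24 lists with at least 5 tested members. List members were also adjusted over the list alone. The lists covered SASP cytokines and chemokines, SASP proteases and growth factors, p53 targets, proliferation, senescence state, fibrillar and interstitial matrix, basement membrane, contractile and SRF targets, YAP and TAZ targets, integrins and focal adhesion, TGF-beta response, interferon-stimulated genes, NF-kB targets, immediate early genes, cholesterol synthesis, lipid storage, glycolysis and hypoxia, endoplasmic reticulum stress, NRF2 targets and lysosome. Markers of epithelial, endothelial, leukocyte and pericyte cells, and mitochondrially encoded, ribosomal protein and histone genes, checked the make-up of the RNA.

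Totals averaged 6628486 ± 552710 expected counts at 100 nM and 2446799 ± 211931 at 250 nM (SD, n = 6 each). The common biological coefficient of variation was 0.299. The median standard error of a log2 change was 0.33 for gel at 100 nM, 0.36 at 250 nM, 0.25 over both doses, 0.49 for the difference and 0.35 for each dose comparison. Shares of a library carry 95% Wilson intervals and a count of 0 an upper limit of 3 counts, both covering counting error alone.

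The edgeR test was tried on simulated data with 200 changed genes. It recovered 2%, 24%, 74% and 91.8% of changes of 1.5, 2, 4 and 8-fold for gel at 100 nM, and 4.26%, 12%, 63.3% and 91.5% at 250 nM. Over both doses it recovered 6.52%, 44.9%, 87.8% and 93.6%, and for the difference 0%, 6%, 31.9% and 65.3%. For dose on plastic it recovered 0%, 16%, 62.5% and 75.5%, and on gel 2%, 10.2%, 57.1% and 89.8%. False calls were 5, 3, 2, 0, 1 and 4 in that order, and with no simulated change 0 genes were called in each. These simulations drew each gene independently from 1 mean profile for all libraries. They held no library that stands apart, no GC content trend and no difference between library sets, unlike the data. At 100 nM, limma-voom recovered 4%, 14%, 68% and 91.8%, and DESeq2 4%, 40%, 80% and 92% with 14 false calls.

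Alternatives were other size factors (RLE, upper quartile), DESeq2 1.42.0, limma-voom with sample weights or a weight per dose, limma-trend on log2 TPM with 0.5 added, no filter, a filter of 1 CPM in 3 libraries, the 6 compared libraries alone, thinning to the smallest total, a log2 change over 1, no mitochondrial genome, the replicate number as a block, and each library left out in turn. Chosen after the data were seen were removal of the trend on GC content or on transcript length, leaving out pairs of libraries, leaving out ribosomal RNA loci, and protein-coding genes alone. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 prepared tables and figures.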

Results

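Polyadenylated RNA of IMR90 cells, an established line of human fetal lung fibroblasts, was sequenced after exposure to doxorubicin, a DNA-damaging anthracycline used to induce senescence. Cells grew on plastic or on a soft gel of 2 kPa and received 100 nM or 250 nM of the drug, which gave 4 groups with 3 libraries each, 12 libraries in all. The series title places the question in how the stiffness of the substrate shapes the secretory phenotype and the transcriptome of senescent fibroblasts. No untreated library was among the 12, so values compare substrates and doses, not drug with vehicle. The total of expected counts ran from 5887056 to 7351916 per library at 100 nM and from 2229069 to 2730309 at 250 nM. Dose was fully confounded with the library set: the names of the deposited 250 nM files mention molecular identifiers, those of the 100 nM files do not. P-values measured the spread between these samples, since nothing in the labels says whether replicates were separate cultures.

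The cells expressed fibroblast genes at high levels, with FN1, the gene of fibronectin, at 4711 ± 195 CPM (SD, n = 3) on plastic at 100 nM. Leukocyte markers were scarce, while some markers of the other cell types were present. Of the 14 leukocyte markers 0 passed the expression filter, and the most abundant, FCER1G, averaged 0.554 CPM over the 12 libraries. Of 12 endothelial markers 1 was tested, TEK at 21.2 CPM, and of 14 epithelial markers 4, led by KRT18 at 71.0 CPM, a keratin gene that fibroblasts also express. Of 10 pericyte and smooth muscle markers 5 were tested, led by CSPG4 at 54.4 CPM. A cluster of 3 loci on chromosome 21 (FP236383.2, FP236383.3 and FP671120.3), a region of ribosomal DNA repeats, took 24.5% ± 5.44 of the counts at 100 nM and 23.6% ± 5.26 at 250 nM (SD, n = 6 each). That share was low in replicate 1 of plastic at 100 nM, at 14.3% (95% Wilson interval 14.3 to 14.4), and in replicate 1 of gel at 250 nM, at 13.2% (13.1 to 13.2). Such intervals cover counting error alone. The latter library also held the most mitochondrial messenger RNA, 8.11% of protein-coding counts (8.08 to 8.15), and the most ribosomal protein messenger RNA, 10.45% (10.41 to 10.49). Its mean correlation with its own group, across genes, was 0.849, against 0.905 to 0.963 in the other 11 libraries. The first principal component held 36.8% of the variance and parted the doses, and the second held 19.9%.

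**Figure D1:**
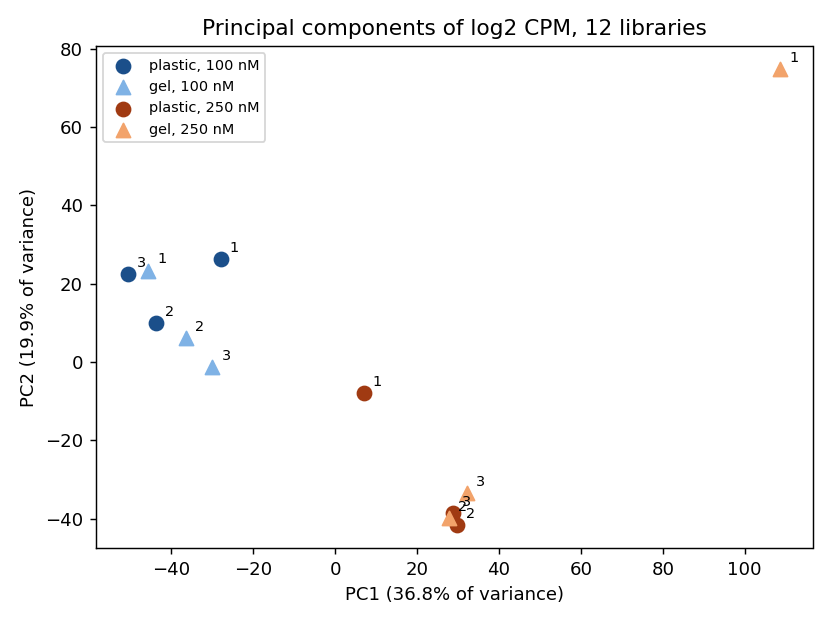
Principal components of log2 CPM of the 12329 tested genes, with PC1 on the x axis (36.8% of the variance) and PC2 on the y axis (19.9%). Each point is a library, numbered by replicate, circles are plastic and triangles gel, blues 100 nM and brown or orange 250 nM. All 6 libraries at 100 nM lie below 0 on PC1, all 6 at 250 nM above it, and replicate 1 of gel at 250 nM lies apart at 109.

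At 100 nM of doxorubicin, fibroblasts on gel held less messenger RNA of the collagen-rich matrix and more of a collagenase than those on plastic. COL1A1, the gene of the main fibrillar collagen chain, stood at 1754 ± 77.0 CPM on plastic and 492 ± 67.0 on gel (SD, n = 3 each), 3.57-fold lower. COL3A1, a second fibrillar collagen, fell 6.88-fold from 159 ± 26.1 to 23.2 ± 11.6 CPM, and DCN, the gene of the proteoglycan decorin, fell 4.30-fold from 424 ± 84.5 to 98.5 ± 28.5. MMP1, the interstitial collagenase, rose 6.31-fold from 60.8 ± 16.5 to 384 ± 151 CPM, and STC1, a secreted glycoprotein hormone, rose 4.10-fold from 596 ± 157 to 2441 ± 1170. CAV1, a structural protein of caveolae, fell 2.24-fold from 1474 ± 119 to 658 ± 75.9 CPM.

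Over all 12329 genes tested, 27 changed between gel and plastic at 100 nM, 8 up and 19 down (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05). The 3 libraries of each group did not overlap in 27 of the 27, where chance gives 10% of genes and 19.0% of all tested genes had no overlap. The largest rises met by the naming rule were SLC6A15 (7.81-fold, adjusted p = 0.0208), MMP1 (adjusted p = 0.00251), SLC16A6 (5.13-fold, 0.0376), STC1 (0.0131) and SH3TC2 (4.03-fold, 0.0224). The largest falls were CEMIP, a hyaluronan-degrading protein (18.6-fold, adjusted p = 0.0208), COL3A1 (0.0208), the chemokine gene CCL2 (4.90-fold, 0.0342), GALNT15 (4.53-fold, 0.0396) and DCN (0.00415). CEMIP stood at 11.9 ± 4.66 CPM on plastic and 0.638 ± 0.568 on gel, so its fold rests on a gel value near the floor of counting. COL1A1 (ENSG00000108821) lies on chromosome 17 at 50183289 to 50201632 and COL3A1 (ENSG00000168542) on chromosome 2 at 188974320 to 189012746 (GENCODE 29, GRCh38). DCN (ENSG00000011465) lies on chromosome 12 at 91140484 to 91183123 and MMP1 (ENSG00000196611) on chromosome 11 at 102789920 to 102798160. STC1 (ENSG00000159167) lies on chromosome 8 at 23841915 to 23854807 and CAV1 (ENSG00000105974) on chromosome 7 at 116524785 to 116561184. Single libraries moved the count. It was 8, 5 and 12 without replicates 1, 2 and 3 of plastic at 100 nM and 10, 11 and 7 without those of gel at 100 nM. It was 11 without either replicate 2 or 3 of plastic at 250 nM, and 119 and 14 without replicates 1 and 3 of gel at 250 nM. DESeq2 called 149 genes, limma-voom with sample weights 473 and limma-trend on TPM 7, while COL1A1, DCN, LUM and MMP1 were called in all 29 settings run. Calls were less stable for STC1 and CAV1 (24 settings), COL3A1 (23), SLC6A15 (22), CEMIP (20), GALNT15 (18), CCL2 (17), IGFBP5 and SH3TC2 (16) and SLC16A6 (15). On the log2 scale SLC16A6, at 2.36, was at 1.57 without replicate 1 of gel at 100 nM, CEMIP, at -4.22, at -3.62 without replicate 3, and GALNT15, at -2.18, at -2.82 without replicate 2. Over the settings the log2 change ran from -5.38 to -1.89 for CEMIP and from 0.72 to 2.23 for SH3TC2, both weakest with limma-trend on log2 TPM, where the fall of CEMIP was smaller than the weakest of COL3A1, -2.46. It ran from 2.27 to 3.51 for SLC6A15, from 1.57 to 2.67 for SLC16A6 and from -2.82 to -1.86 for GALNT15.

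Of the lists fixed before the data were examined, the fibrillar and interstitial matrix genes fell at 100 nM, with 34 of 41 members negative and a median log2 change of -0.78 (camera, adjusted p = 1.27e-19, and 0.00142 with an estimated correlation). Of its members 8 fell over all genes and 17 adjusted over the list alone. The median was -0.47 without replicate 1 of plastic at 100 nM. The 8 called members became 4, 3 and 4 without replicates 1, 2 and 3 of plastic at 100 nM and 4, 3 and 3 without those of gel at 100 nM. They became 4 without replicate 2 or 3 of plastic at 250 nM, 5 without replicate 3 of gel at 250 nM and 13 without replicate 1 of both gel groups. DESeq2 and the unfiltered fit called 14 each, limma-voom with sample weights 15, edgeR on the 6 libraries alone 5 and limma-trend on log2 TPM 3. Beside COL1A1, COL3A1 and DCN they included LUM, the gene of lumican, at 4.17-fold lower (adjusted p = 0.00257). No other list held with an estimated correlation at this dose. The proliferation genes were negative in 39 of 39 members with a median of -0.87, but 0 were called over all genes and 1 adjusted over the list alone (camera, adjusted p = 1.09e-11, and adjusted p = 0.324 with an estimated correlation). Contractile and SRF target genes went down by camera with 0 of 35 called and 2 adjusted over the list alone (adjusted p = 4.77e-06, and 0.238 with an estimated correlation). Interferon-stimulated genes were negative in 22 of 24 members with 0 called either over all genes or adjusted over the list alone (adjusted p = 1.2e-06, and 0.261 with an estimated correlation). YAP and TAZ targets, read-outs of mechanical signalling, had 0 of 22 called and 0 adjusted over the list alone (adjusted p = 0.00484, and 0.253 with an estimated correlation), and adjusted p = 0.0624 without replicate 1 of both gel groups. Senescence state genes had 0 of 18 called and 0 adjusted over the list alone (down, adjusted p = 0.00877, and 0.253 with an estimated correlation), and ribosomal protein genes 0 of 75 and 0 (down, adjusted p = 0.000309, and 0.541 with an estimated correlation).

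The genes of the senescence-associated secretory phenotype (SASP) went both ways at 100 nM. Proteases and growth factors went up by camera (adjusted p = 0.000123, and 0.238 with an estimated correlation), with MMP1 and STC1 up and IGFBP5, a binding protein of insulin-like growth factors, down 1.95-fold (adjusted p = 0.0208) among 39 tested; adjusted over the list alone, 11 rose and 3 fell. Cytokines and chemokines showed no change as a list (camera, adjusted p = 0.587), with a median log2 change of -0.07 and a mean of 1.04; CCL2 fell, and adjusted over the list alone 3 rose and 1 fell. The chemokine CXCL8 stood at 7.94 ± 6.05 CPM on plastic and 78.9 ± 116 on gel (SD, n = 3 each; adjusted p = 0.489), and the cytokine IL1B at 1.16 ± 0.784 and 45.1 ± 69.2 (adjusted p = 0.191), both highest in replicate 1 of gel. IL6 did not pass the filter, with 14, 10 and 14 counts on plastic and 68, 13 and 11 on gel. MMP3, stromelysin 1, stood at 1.07 ± 1.04 CPM on plastic and 62.5 ± 79.7 on gel and did not pass (adjusted p = 0.0725). The cell-cycle inhibitor CDKN1A stood at 504 ± 88.4 and 644 ± 155 CPM (adjusted p = 0.635), CDKN2A at 41.8 ± 28.5 and 35.6 ± 25.6 (0.957), and LMNB1, a lamin gene low in senescent cells, at 53.8 ± 21.7 and 16.5 ± 7.68 (0.36).

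At 250 nM, COL1A1 again stood lower on gel, at 597 ± 143 CPM against 2347 ± 326 on plastic (SD, n = 3 each), 3.94-fold lower. It was the single gene called of 12329 (edgeR quasi-likelihood, adjusted p = 0.00219), lower in 3 of 3 gel libraries, while 1224 genes had an unadjusted p under 0.05. Matrix genes fell as a list, with a median log2 change of -0.57 and 33 of 41 members negative (camera, adjusted p = 2.06e-12, and 0.00979 with an estimated correlation); 1 fell over all genes and 9 adjusted over the list alone. That 1 became 2 without replicate 1 of gel at 250 nM, 3 without both libraries that stand apart and 4 without replicate 1 of both gel groups. It was 8 with DESeq2, 10 with limma-voom and sample weights (median -0.37), 10 with no filter, 3 with the GC content trend removed and 0 on the 6 libraries alone. It was 2 with upper-quartile scaling, with thinning, with no mitochondrial genome and with the transcript length trend removed. Cholesterol synthesis genes rose as a list, 23 of 24 positive with a median of 0.74 (adjusted p = 5.11e-13, and 0.0107 with an estimated correlation), with 0 called over all genes (3 by DESeq2, 11 by limma-voom with sample weights, 1 with no filter and 2 without replicate 1 of both gel groups) and 12 adjusted over the list alone. NRF2 targets, genes of the antioxidant response, rose as a list with a median of 0.37 (adjusted p = 0.000267, and 0.0233 with an estimated correlation), with 0 of 17 called over all genes and 1, NQO1, adjusted over the list alone.

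Named genes that did not pass at 250 nM included MMP1 at 136 ± 30.3 CPM on plastic and 359 ± 23.2 on gel (adjusted p = 0.19), STC1 at 1198 ± 137 and 2189 ± 164 (0.324), COL3A1 at 72.5 ± 26.0 and 19.7 ± 13 (0.213) and CDKN1A at 655 ± 130 and 1216 ± 84.7 (0.213). CXCL8 stood at 4.96 ± 5.78 and 35.4 ± 52.3 CPM (adjusted p = 0.6) and IL1B at 2.40 ± 1.55 and 9.76 ± 8.25 (0.676), again highest in replicate 1 of gel. IL6 had 1, 0 and 2 counts in the plastic libraries and 0 in the 3 gel libraries, which allows up to 0.405 CPM over the gel group. DESeq2 called 89 genes at this dose, limma-voom with sample weights 192 and the unfiltered fit 181, and edgeR on the 6 libraries alone called 0 (730 at an unadjusted p under 0.05). COL1A1 was called in 28 of 29 settings, with adjusted p up to 0.133. The count was 6 without replicate 1 of gel at 250 nM, the library apart from the rest, and 2 without replicate 2.

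Other lists passed at 250 nM with the preset correlation and not with an estimated one. Interferon-stimulated genes went down, with 0 of 24 called and 7 adjusted over the list alone (camera, adjusted p = 1.16e-08, and 0.196 with an estimated correlation). Proliferation genes went down with 0 of 39 called and 0 adjusted over the list alone (adjusted p = 1.64e-05, and 0.396 with an estimated correlation), and had adjusted p = 0.308 without replicate 1 of plastic at 250 nM. Contractile genes went down with 0 of 35 called and 0 adjusted over the list alone (adjusted p = 0.000261, and 0.27 with an estimated correlation). YAP and TAZ targets went down with 0 of 22 called and 4 adjusted over the list alone (adjusted p = 0.000611, and 0.174 with an estimated correlation).

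Ribosomal protein genes went up at 250 nM with 0 of 75 called and 0 adjusted over the list alone (camera, adjusted p = 1.48e-06, and 0.354 with an estimated correlation). Mitochondrially encoded genes went up with 0 of 13 called and 2 adjusted over the list alone (adjusted p = 3.31e-05, and 0.27 with an estimated correlation). Both are the gene sets whose shares, 10.45% and 8.11%, were highest in gel replicate 1. For p53 targets, 0 of 33 were called and 1 rose adjusted over the list alone (adjusted p = 0.0228, and 0.27 with an estimated correlation). For lipid storage genes, 0 of 17 were called and 0 adjusted over the list alone (up, adjusted p = 0.0305, and 0.174 with an estimated correlation). SASP cytokines had 0 of 15 called and 1 up adjusted over the list alone (adjusted p = 0.048, and 0.306 with an estimated correlation). SASP proteases had 0 of 39 called, with 2 up and 1 down adjusted over the list alone (up, adjusted p = 0.048, and 0.354 with an estimated correlation), a call that ended in 9 of the 19 settings run for lists, with adjusted p up to 0.206. Lysosome genes had 0 of 29 called and 1 up adjusted over the list alone (adjusted p = 0.048, and 0.354 with an estimated correlation).

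Averaged over both doses, each taken within its own library set, COL1A1, COL3A1, DCN and CAV1 stood lower on gel and MMP1, STC1 and HMGCS1 higher. COL1A1 was 3.75-fold lower on gel (adjusted p = 4.12e-05), COL3A1 4.98-fold (0.00523), DCN 3.19-fold (0.000748), POSTN, the gene of periostin, 2.75-fold (0.0207) and CAV1 2.06-fold (0.000748). ACTA2, the smooth muscle actin of myofibroblasts, was 2.40-fold lower (adjusted p = 0.0346), from 210 ± 68.1 to 76.5 ± 37.5 CPM at 100 nM and from 378 ± 64.4 to 179 ± 27.8 at 250 nM (SD, n = 3 each). MMP1 was 4.07-fold higher (adjusted p = 0.000626), MMP3 19.0-fold (0.0207), STC1 2.74-fold (0.00523) and SERPINB2, a protease inhibitor, 2.06-fold (0.04). HMGCS1, SQLE and SC5D, enzymes of cholesterol synthesis, were 1.81-fold, 1.61-fold and 1.69-fold higher (adjusted p = 0.00703, 0.0176 and 0.0376).

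**Figure D2:**
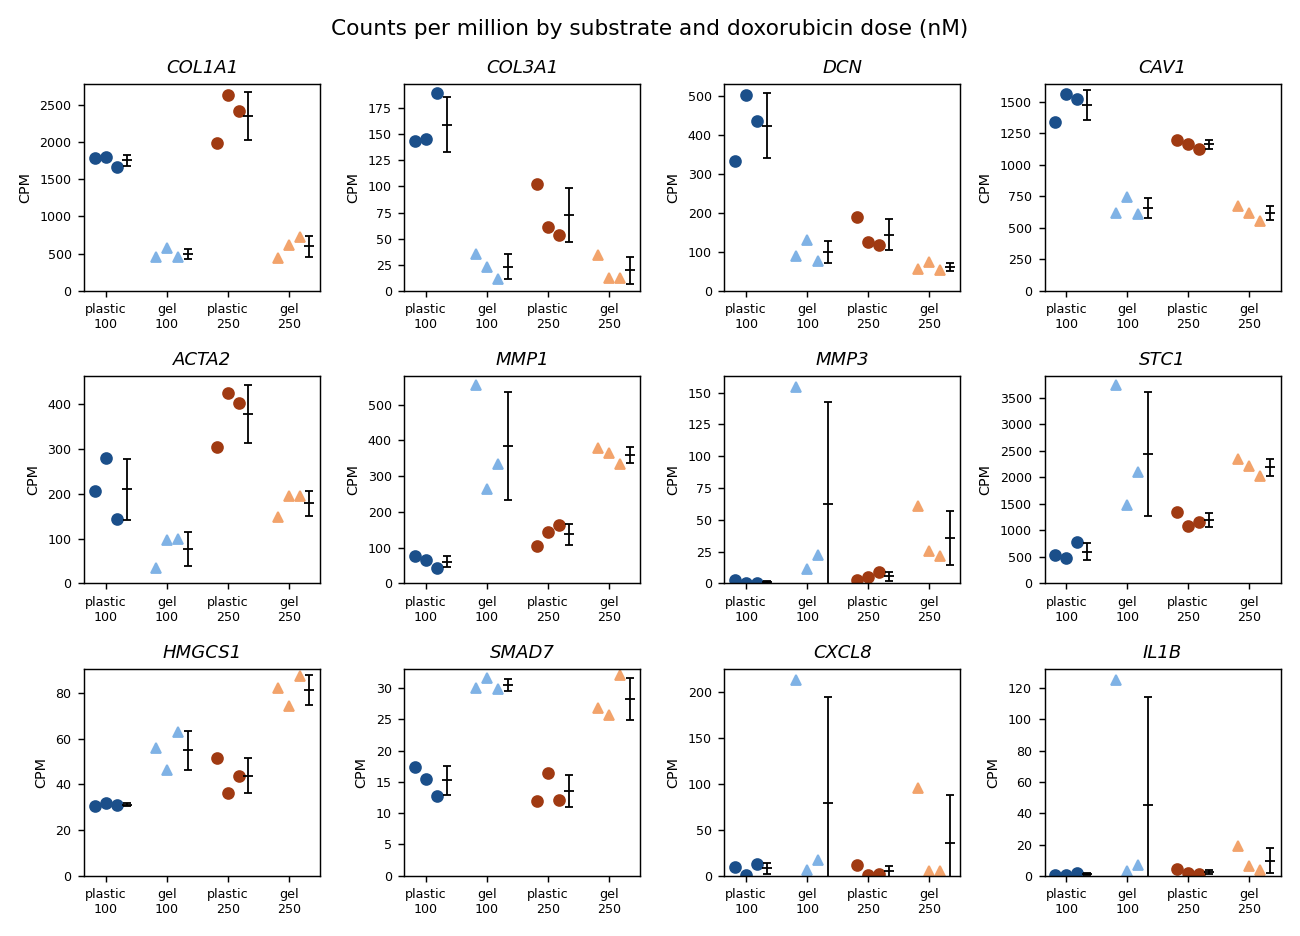
CPM of 12 genes (y axis, linear, from 0) in the 4 groups of substrate and doxorubicin dose in nM (x axis); points are libraries and bars the mean ± SD of 3. COL1A1 lies at 1754 ± 77.0 on plastic and 492 ± 67.0 on gel at 100 nM and at 2347 ± 326 and 597 ± 143 at 250 nM, while CXCL8 and IL1B, not called, are highest in replicate 1 of each gel group. Error bars that reach below 0 end at the axis.

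In this comparison 98 of 12329 genes changed, 36 up and 62 down (edgeR quasi-likelihood), and in 91 of the 98 the groups did not overlap at either dose, as in 3.75% of all tested genes. The calls of CAV1, COL1A1, COL3A1, DCN, MMP1 and STC1 stood in 29 of 29 settings, that of HMGCS1 in 28 and that of SMAD7 in 27. Less stable were SQLE (20 settings), POSTN (19), CRIM1 (18), MMP3, ACTA2 and SC5D (17), NQO1 and TGFB2 (14) and SERPINB2 (13). The count was 65 and 40 without replicates 1 and 2 of plastic at 100 nM and 40 without replicate 3 of gel at 100 nM. It was 46, 38 and 41 without replicates 1, 2 and 3 of plastic at 250 nM, and 262, 62 and 50 without those of gel at 250 nM. DESeq2 called 330 and limma-voom with sample weights 811. The log2 change of MMP3, 4.25, ran from 2.98 to 4.85 over the settings, with 3.30 without replicate 1 of gel at 100 nM and 4.85 without replicate 1 of plastic at 100 nM. MMP1 and MMP3 lie opposite exons of WTAPP1 and ACTA2 opposite ACTA2-AS1 and FAS, and how strands were counted is not stated, so reads of the partner cannot be told from theirs. The same holds for CEMIP, SLC16A6, IGFBP5, HMGCS1, NQO1, CRIM1, CDKN1A, CDKN2A, CCN2 and CSPG4, which also have exons of another gene opposite.

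Matrix genes held over both doses with an estimated correlation (median log2 change -0.57, 35 of 41 negative; camera adjusted p = 3.66e-25, and 0.000685 with an estimated correlation), with 12 called down over all genes and 20 adjusted over the list alone. Cholesterol synthesis genes did so as well (median 0.61, 22 of 24 positive; adjusted p = 6.36e-13, and 0.0149 with an estimated correlation), with 3 called up over all genes and 14 adjusted over the list alone. Those 3 became 1 without replicate 2 of plastic or 3 of gel at 100 nM, without any 1 replicate of plastic at 250 nM, or without replicate 2 or 3 of gel at 250 nM. They became 6 and 9 without replicate 1 of gel at 100 nM and at 250 nM, 10 without both libraries that stand apart and 11 without replicate 1 of both gel groups. DESeq2 and the unfiltered fit called 8 each, limma-voom with sample weights 14, edgeR with the GC content trend removed 5 and limma-trend on log2 TPM 0. At 100 nM by itself 0 of them were called (2 by DESeq2, 5 by limma-voom with sample weights, 2 without replicate 1 of gel at 250 nM and 4 without replicate 1 of both gel groups) and 3 rose adjusted over the list alone (adjusted p = 0.000172, and 0.238 with an estimated correlation). Proteases and growth factors of the secretory phenotype had 4 up and 1 down over all genes and 12 up and 4 down adjusted over the list alone (adjusted p = 0.000132, and 0.106 with an estimated correlation). Of the TGF-beta response genes SMAD7, an inhibitor of that pathway, rose 2.04-fold (adjusted p = 0.00624) and the ligand gene TGFB2 fell 2.06-fold (0.0383), with 2 up and 1 down adjusted over the list alone and no change of the list (camera, adjusted p = 0.5).

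**Figure D3:**
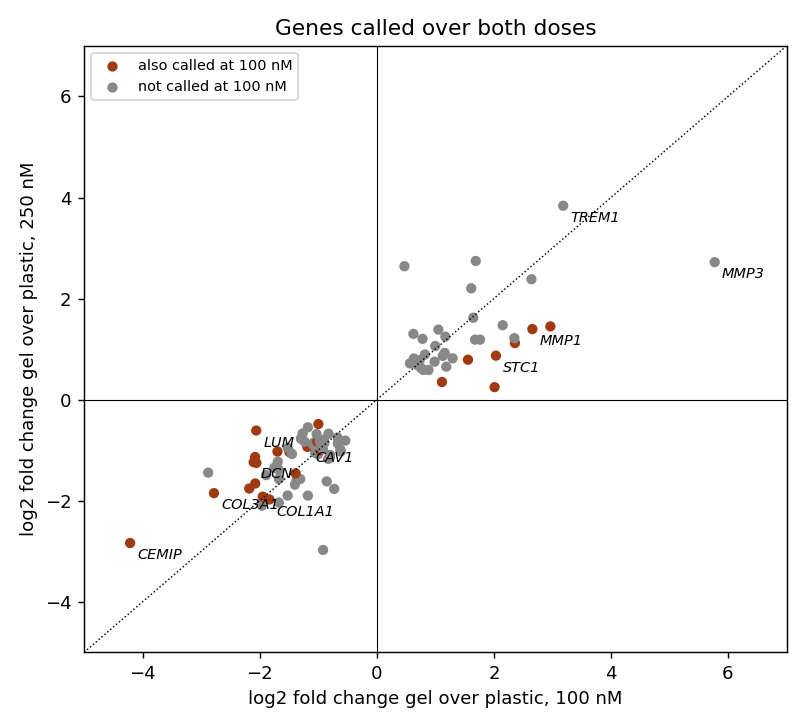
Log2 fold change of gel over plastic at 100 nM (x axis) and at 250 nM (y axis) of the 98 genes called over both doses; each point is a gene, brown where it was also called at 100 nM, and the dotted line marks equal change. All 98 lie on the same side of 0 at both doses, which follows in part from how they were chosen.

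YAP and TAZ targets had TGFB2 and CRIM1, a regulator of growth factor release, down (CRIM1 1.70-fold, adjusted p = 0.04), with 1 up and 6 down adjusted over the list alone (camera, adjusted p = 4.65e-05, and 0.0965 with an estimated correlation). CCN1 and CCN2, well-known YAP targets, did not pass (adjusted p = 0.171 and 0.244), nor did ANKRD1 (0.998). Contractile genes had ACTA2 down, with 8 down adjusted over the list alone (adjusted p = 7.5e-08, and 0.105 with an estimated correlation). Interferon-stimulated genes had 0 called, with 11 down adjusted over the list alone (adjusted p = 2.65e-12, and 0.105 with an estimated correlation), and proliferation genes 0, with 7 down adjusted over the list alone (1.96e-12, and adjusted p = 0.255 with an estimated correlation). NRF2 targets had NQO1 up 1.56-fold (adjusted p = 0.0476), 2 up adjusted over the list alone (list adjusted p = 0.00242, and 0.058 with an estimated correlation). Mitochondrially encoded genes had MT-ND2, a subunit of respiratory complex I, up 1.61-fold (adjusted p = 0.0132), 1 up adjusted over the list alone (list adjusted p = 0.000132, and 0.301 with an estimated correlation). For p53 targets, 0 were called and 1, CDKN1A, rose adjusted over the list alone (adjusted p = 0.00695, and 0.205 with an estimated correlation). For lipid storage genes, 0 were called, with 3 up and 1 down adjusted over the list alone (adjusted p = 0.0325, and 0.105 with an estimated correlation).

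Other lists did not pass over both doses. SASP cytokines had 0 called, with 4 up and 2 down adjusted over the list alone (camera, adjusted p = 0.0827). Senescence state genes had 0 called, with 2 up and 1 down adjusted over the list alone (adjusted p = 0.0967), and glycolysis and hypoxia genes 0, with 3 up and 2 down adjusted over the list alone (0.169). Integrin and focal adhesion genes had CAV1 down, with 2 up and 5 down adjusted over the list alone (adjusted p = 0.241), and basement membrane genes 0, with 2 down adjusted over the list alone (0.5). Lysosome and autophagy genes (adjusted p = 0.0967), immediate early genes (0.169), pericyte and smooth muscle markers (0.431) and NF-kB targets (0.431) had 0 called over all genes and 0 adjusted over the list alone. So did ribosomal protein genes (adjusted p = 0.5), endoplasmic reticulum stress genes (0.703) and replication-dependent histone genes (0.703). GDF15, a stress-induced cytokine, stood at 56.4 ± 16.9 and 121 ± 75.4 CPM at 100 nM and at 119 ± 63.4 and 231 ± 202 at 250 nM (SD, n = 3 each; adjusted p = 0.332 over both doses). CDKN1A (adjusted p = 0.0798), CDKN2A (0.98), LMNB1 (0.544), MKI67 (0.276), CXCL8 (0.244) and IL1B (0.112) did not pass either.

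Whether the substrate effect differed between doses was tested directly, with 0 of 12329 genes called (edgeR quasi-likelihood, smallest adjusted p = 0.755; 771 at an unadjusted p under 0.05). DESeq2 called 0 (938 at an unadjusted p under 0.05) and limma-voom with sample weights 0 (1111), while the fit with no expression filter called 63. The 27 genes called at 100 nM, COL1A1, MMP1 and the others named there, had the same sign at 250 nM in 27 of 27 and an unadjusted p under 0.05 there in 23. COL1A1 was called at both doses, 1 shared gene where 0.00154 would be expected by chance. That expectation assumes independent calls, while the comparisons share the fitted spread of each gene, and it rests on 1 gene. Across all genes the 2 sets of log2 fold changes had a Pearson r of 0.18 and a Spearman rho of 0.14, with the same sign in 52.9%; genes are not independent replicates. The test recovered 65.3% of simulated 8-fold differences of this kind and 6% of 2-fold ones, and the difference is between library sets as much as between doses. As lists, with 0 members called over all genes and 0 adjusted over the list alone in each, 3 passed with the preset correlation. Cholesterol synthesis genes had a median difference of 0.30, gel changes being higher at 250 nM (camera, adjusted p = 0.0174, and 0.553 with an estimated correlation). Endoplasmic reticulum stress genes had a median difference of 0.61 (adjusted p = 0.0174, and 0.646 with an estimated correlation) and ribosomal protein genes 0.44 (adjusted p = 4.93e-12, and 0.553 with an estimated correlation).

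On plastic, libraries of cells given 250 nM held fewer transcripts of KIF20A, TTK, LMNB1 and H4C3 than those given 100 nM, and more of FUCA1 and ADM. KIF20A, a kinesin of cell division, stood at 21.4 ± 3.49 CPM at 100 nM and 2.82 ± 1.55 at 250 nM (SD, n = 3 each), 7.52-fold lower (adjusted p = 0.00476), and the checkpoint kinase TTK fell 7.74-fold (0.0179). LMNB1 fell 11.2-fold from 53.8 ± 21.7 to 4.8 ± 4.57 CPM (adjusted p = 0.0128) and the histone gene H4C3 9.62-fold from 413 ± 151 to 42.8 ± 36.1 (0.00659). FUCA1, a lysosomal fucosidase, rose 4.05-fold from 4.59 ± 2.61 to 18.7 ± 2.60 CPM (adjusted p = 0.0145), and ADM, the hypoxia-induced adrenomedullin gene, rose 3.01-fold from 77.7 ± 11.3 to 234 ± 44.5 (0.00179). Without replicate 1 of plastic at 250 nM the log2 changes of TTK, LMNB1 and H4C3 were -4.23, -4.63 and -4.24, against -2.95, -3.48 and -3.26 with it. Their weakest values over the settings were -2.45, -3.02 and -2.93.

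Between doses on plastic 1061 of 12329 genes changed, 504 up and 557 down (edgeR quasi-likelihood), and dose cannot be told apart from library set here. The make-up of the RNA differed too: mitochondrial ribosomal RNA took 6.52% ± 0.369 of the counts on plastic at 100 nM and 2.99% ± 0.238 at 250 nM, and mitochondrial messenger RNA 3.29% ± 0.741 and 4.60% ± 0.327 of protein-coding counts (SD, n = 3 each). Proliferation genes fell, 13 of 39 over all genes and 30 adjusted over the list alone (camera, adjusted p = 3.69e-15, and 0.386 with an estimated correlation). Lysosome genes had 7 of 29 up, and 7 up and 1 down adjusted over the list alone (adjusted p = 0.0177, and 0.386 with an estimated correlation). Glycolysis and hypoxia genes had 4 of 28 up and 4 adjusted over the list alone (adjusted p = 0.0177, and 0.401 with an estimated correlation). Senescence state genes had FUCA1 up and 4 down, among them LMNB1 and HMGB2 (3.81-fold, adjusted p = 0.0108). Adjusted over the list alone, 2 rose and 7 fell (list down, adjusted p = 0.0177, and 0.386 with an estimated correlation). Ribosomal protein genes had 6 of 75 up, and 10 up and 2 down adjusted over the list alone (adjusted p = 0.0319, and 0.752 with an estimated correlation). Lists that did not pass included histone genes, with 1 up and 5 down of 16, and 1 up and 6 down adjusted over the list alone (adjusted p = 0.0556), and mitochondrially encoded genes, with 3 up of 13, and 4 up and 1 down adjusted over the list alone (0.0823). Of the secretory genes CCL2 fell 4.70-fold (adjusted p = 0.0104) and TIMP2, an inhibitor of metalloproteinases, rose 2.21-fold (0.00597). The largest rise, CLVS1 (from 0.411 ± 0.254 to 34.1 ± 16.5 CPM, adjusted p = 0.0164; log2 change 3.78 to 6.76 over the settings), lies opposite exons of ASPH and is uncertain while strand counting is not stated, as are KIF20A and TIMP2, which have such partners too. The count was 650, 513 and 690 without replicates 1, 2 and 3 of plastic at 100 nM. It was 118 and 127 without replicates 2 and 3 of plastic at 250 nM, 2228 without replicate 1 of gel at 250 nM, and 3193 with limma-voom and sample weights.

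On gel, BUB1B, NCAPG, H4C3 and MYOF stood lower at 250 nM than at 100 nM, and AEN and RPL35 higher. BUB1B, a mitotic checkpoint kinase, fell 13.5-fold from 9.52 ± 6.22 to 0.693 ± 0.50 CPM (SD, n = 3 each; adjusted p = 0.00929), NCAPG, a condensin subunit, 19.0-fold from 24.1 ± 12.8 to 1.35 ± 1.17 (0.0093) and H4C3 12.6-fold from 219 ± 86.4 to 17.5 ± 6.78 (0.00465). RPL35, a ribosomal protein, stood at 216 ± 8.43 CPM at 100 nM and 559 ± 108 at 250 nM and was called in 29 of 29 settings, but exons of WDR38 lie opposite and its value is uncertain while strand counting is not stated. AEN, a p53-induced nuclease, rose 2.42-fold (adjusted p = 0.00488) and MYOF, a YAP target, fell 2.32-fold (0.00465). The log2 change of BUB1B, -3.75, was -3.12 without replicate 1 of gel at 100 nM and -4.51 without replicate 3 of gel at 250 nM. That of NCAPG, -4.25, was -3.57 and -4.86 without replicates 1 and 3 of gel at 250 nM. Over the settings BUB1B ran from -4.51 to -2.49, NCAPG from -4.86 to -3.07 and MYOF from -1.84 to -1.03.

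Between doses on gel 1703 of 12329 genes changed, 853 up and 850 down (edgeR quasi-likelihood), again with dose and library set not to be told apart. Ribosomal protein genes had 32 up and 1 down of 75, and 43 up and 1 down adjusted over the list alone (camera, adjusted p = 1.47e-14, and 0.278 with an estimated correlation). Mitochondrially encoded genes had 7 up and 1 down of 13, and 7 up and 2 down adjusted over the list alone (adjusted p = 0.00417, and 0.417 with an estimated correlation). Both sets had their highest shares in gel replicate 1 at 250 nM. Mitochondrial ribosomal RNA took 7.48% ± 0.350 of the counts on gel at 100 nM and 3.34% ± 0.590 at 250 nM (SD, n = 3 each). Proliferation genes had 17 of 39 down and 20 adjusted over the list alone (adjusted p = 8.18e-09, and 0.4 with an estimated correlation). Cholesterol synthesis genes had 7 of 24 up and 8 adjusted over the list alone (adjusted p = 0.000449, and 0.278 with an estimated correlation).

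Glycolysis and hypoxia genes had 8 up and 1 down of 28 on gel, and 11 up and 1 down adjusted over the list alone (camera, adjusted p = 0.000792, and 0.278 with an estimated correlation). Lysosome genes had 8 of 29 up, and 8 up and 1 down adjusted over the list alone (adjusted p = 0.000792, and 0.278 with an estimated correlation). Lipid storage genes had 2 of 17 up and 2 adjusted over the list alone (adjusted p = 0.0223, and 0.278 with an estimated correlation). Histone genes had 7 of 16 down, and 2 up and 7 down adjusted over the list alone (adjusted p = 0.0396, and 0.278 with an estimated correlation). YAP and TAZ targets had 6 of 22 down and 7 adjusted over the list alone (adjusted p = 0.0396, and 0.375 with an estimated correlation). Of the p53 targets 5 rose and 2 fell of 33, and 7 rose and 3 fell adjusted over the list alone (up, adjusted p = 0.0459, and 0.375 with an estimated correlation).

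The dose changes on the 2 substrates had a Pearson r of 0.62 across genes. On both, 304 genes were up, where 34.9 would be expected by chance, and 286 down, where 38.4 would. Those expectations assume independent calls, while both comparisons set the same library sets against each other and share the fitted spread. The overlap therefore does not tell a dose effect from a difference of library sets. The gel count was 679, 814 and 1030 without replicates 1, 2 and 3 of gel at 100 nM, and 748 without replicate 1 of both gel groups. NCAPG has exons of LCORL opposite. Among the largest rises on gel, RPS6KB2, TLE5, CCDC86 and TUBA1B lie opposite exons of other genes, and their values are uncertain while strand counting is not stated. RPS6KB2 stood at 0.596 ± 1.03 CPM at 100 nM and 40.2 ± 28.0 at 250 nM, while its antisense partner RPS6KB2-AS1 had 735 counts over the 6 libraries at 100 nM and 0 over the 6 at 250 nM.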

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

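The 3 tests on genes missing at 250 nM were chosen after the result was seen, and the 3 tests that remove a GC content or transcript length trend were added after the data were seen. The other tests here were written down before their own results were seen. Those on matrix genes and on the gap in calls still address patterns found in these data, and 1 names a library that stood apart. A test of the difference of the substrate effect between doses singled out 3 gene lists. These were cholesterol synthesis genes (camera, adjusted p = 0.0174), endoplasmic reticulum stress genes (adjusted p = 0.0174) and ribosomal protein genes (adjusted p = 4.93e-12). The changes on gel were more positive at 250 nM in 20 of 24, 21 of 26 and 68 of 75 members. None of the 3 held with an estimated correlation between genes (adjusted p = 0.553, 0.646 and 0.553). Dose and library set cannot be told apart for them.

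Matrix genes stood lower on gel over both doses, with a median log2 change of -0.57. The tables argue against a GC content trend between libraries as the whole cause, since the median was -0.58 with that trend removed. They argue against a trend on transcript length, with -0.51 after removal, and against a single library that stands apart, since the weakest median without 1 library was -0.48 (without plastic at 250 nM replicate 1). A response of the cells to the soft gel may underlie the pattern, as a hypothesis found on these data that was not itself tested. Whether each replicate was a separate culture stays open.

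Fewer genes were called between gel and plastic at 250 nM, 1, than at 100 nM, 27. Lower depth at 250 nM is argued against, since thinning every library to the smallest total gave 25 calls at 100 nM, 20 of them among the 27. Leaving out the gel library that stands apart, replicate 1 at 250 nM, gave 6 calls at 250 nM, and removing the GC content trend between libraries gave 5. Each lies between what its explanation needs and what would exclude it, judged against the 27 calls with all libraries. Without replicate 1 of gel at 250 nM, however, 119 genes were called at 100 nM, so the gap in counts did not narrow. Whether either explanation accounts for part of the gap cannot be told. The difference between the doses itself had 0 calls by edgeR (771 genes at an unadjusted p under 0.05; 0 by DESeq2 and by limma-voom).

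Of the genes called lower at 250 nM on both substrates, 15 had at most 3 counts over the 6 libraries at that dose. Among these, 11 have exons of another gene opposite, as RPS6KB2-AS1 has those of RPS6KB2. The other 4 have none, which moved reads within a pair leave unexplained. Of the 12227 tested genes with known GC content, 7822 had no counted gene opposite. For the 11, a median of 123 counts (47.2 to 616) was expected at 250 nM from the library totals. Library totals alone would thus have left more than the 3 counts these genes had at most. The genes were chosen by calls already scaled for depth, which shut out a low expectation. The test therefore could not have favoured lower depth and is no evidence against it. Genes opposite a partner at least 10 times more abundant changed by 0.12 more than like genes on plastic and by 0.05 on gel. That argues against different counting of strands for overlaps with such abundant partners. It cannot decide for pairs whose partner fell short of 10 times over the 12 libraries. The partners taken for these 11 genes all fell short, so the test covers none of the pairs in question. AL157871.1, for example, had 264 counts over the 6 libraries at 100 nM and its partner SLC25A29 averaged 0.103 CPM there. The partners, taken by position whatever their level, changed by a median of 1.13 on the log2 scale from 100 to 250 nM, higher in 8 of 11 (TK2 by 0.18), and the pairs' combined counts by a median of -0.21, with -0.65 for AC018362.2, -3.62 for SLC7A14 and -3.76 for GRPR, the 3 whose partners did not rise. This is consistent with reads moved between the 2 genes of most of these pairs, as from a change of annotation or of read assignment between the library sets; an effect of dose was not tested and stays open.

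Other groupings of the libraries were fitted with the same model. For gel against plastic over both doses 1 of 100 groupings, the real one with 98 genes, called as many, and the highest other called 2. This argues against a chance assignment of the libraries, though 1 of 100 is the smallest share these groupings could give. It does not address chance between cultures, since the labels do not say whether replicates were separate cultures. For the other comparisons of 2 groups the 10 splits are too few for a share under 0.05. At 100 nM 1 split called as many, the real one with 27 genes (highest other 1), and at 250 nM 2 splits did (real 1, highest other 2). Dose on plastic (real 1061, highest other 0) and dose on gel (real 1703, highest other 0) had 1 split each. For the difference between doses the real count was 0, so 100 of 100 groupings call as many by construction and this comparison decides nothing. The highest other, 98, arose with substrate labels exchanged in 1 dose, which turns the shared substrate effect into a difference and so reflects the structure of the samples.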

How the results depend on the processing

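The 6 counts of called genes, in the order gel at 100 nM, gel at 250 nM, gel over both doses, difference, dose on plastic and dose on gel, were 27, 1, 98, 0, 1061 and 1703; values that moved by over 1.5 times follow. Removal of trends, leaving out pairs of libraries, leaving out ribosomal RNA loci and protein-coding genes alone were chosen after seeing the data. DESeq2 called 149, 89 and 330 in the gel comparisons and limma-voom with sample weights 473, 192 and 811, with 3193 and 2923 for dose. With no filter the counts were 231, 181, 468 and, for the difference, 63. Limma-trend on log2 TPM gave 7, 2 and 52, and 676 for dose on plastic. The 6 compared libraries alone gave 10 and 0 for gel at each dose and 1693 and 516 for dose. For gel at 250 nM, upper-quartile scaling gave 2, thinning to the smallest library 3, no mitochondrial genome 2, removal of the GC content trend 5 and of the transcript length trend 3. Without replicate 1 of both gel groups the counts were 114, 19 and 358, and 2547 and 748 for dose. Without both libraries that stand apart they were 69, 9 and 249, and 2143 for dose on plastic. A log2 change over 1 left 60 over both doses, and 688 and 1090 for dose. With the replicate block 10 genes were called at 100 nM (4 matrix genes, against 8) and 41 over both doses (1 cholesterol synthesis gene, against 3). The labels do not say whether equal numbers pair the libraries. With group means removed, the highest correlation between substrates at 100 nM, 0.39, joined plastic replicate 3 and gel replicate 1. The highest at 250 nM, 0.11, joined replicate 1 of both substrates, so the correlations do not settle it. Leaving out 1 library gave 5 to 119 at 100 nM, 1 to 6 at 250 nM, 38 to 262 over both doses, 0 to 0 for the difference, 118 to 2228 for dose on plastic and 679 to 1861 on gel. DESeq2 called again 27 of the 27 genes at 100 nM and 98 of the 98 over both doses, and the fits without both libraries that stand apart 23 and 85. Replicate 1 of gel at 250 nM is in neither gel at 100 nM nor dose on plastic. Leaving it out can move those counts only through the spread, filter and scaling that all libraries share. Which of these did so, and the cause of the other moves, was not tested.

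Lists called, in the same order, were 9, 14, 11, 3, 5 and 10. With an estimated correlation they were 1, 3, 2, 0, 0 and 0. Without both libraries that stand apart 6 were called for the difference and 8 for dose on plastic, where removal of the GC content trend left 1. Leaving out 1 library gave 8 to 13, 11 to 15, 10 to 13, 1 to 6, 5 to 10 and 8 to 10. The correlation of the gel effect between doses, 0.18, ran from 0.06 to 0.28 when 1 library was left out. Of all values for genes, counts and lists, 5794 stayed on their side, 934 passed below the threshold, 29 above it and 144 moved. Among genes called in the main fit or in the alternative, 0 turned direction. Genes called in neither that turned sign were counted as moved. For gel against plastic these were 15 values at 100 nM, 17 at 250 nM and 25 over both doses.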

Other observations

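The genes in this paragraph lie outside the naming rule and were chosen after their values were seen. Further genes called over both doses went either way. FSTL1, a secreted glycoprotein, fell by 0.93 on the log2 scale (edgeR quasi-likelihood, adjusted p = 0.00553), from 1020.0 ± 178 to 529 ± 51.5 CPM at 100 nM (SD, n = 3 each). EFEMP1, a fibulin of elastic fibres, fell by 1.48 (adjusted p = 0.0227), the heparin-binding growth factor gene PTN by 1.62 (0.0207) and CCN4, a matricellular protein, by 1.94 (0.0055). GJA1, the gap junction protein connexin 43, fell by 0.99 (adjusted p = 0.00704), and PDGFRB, a receptor of platelet-derived growth factor, by 0.85 (0.0452). Higher on gel were TFPI2, a protease inhibitor, by 1.81 (adjusted p = 0.0207), the phosphate transporter SLC20A1 by 1.17 (0.00523) and G0S2, an inhibitor of fat breakdown, by 2.22 (0.0251).

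The cytokine genes CXCL8 and IL1B were highest in replicate 1 of each gel group, CXCL8 at 213 CPM at 100 nM and 95.8 at 250 nM, IL1B at 125 and 19.2. They did not pass in any gel comparison, and replicate 1 of gel at 250 nM is also the library that stands apart. IL6 was counted 14, 10 and 14 times on plastic and 68, 13 and 11 times on gel at 100 nM. At 250 nM it was counted 1, 0 and 2 times on plastic and 0 times in each gel library, so both substrates lay at the floor of counting there.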
